A study of Camponotus floridanus with 24 samples.

How the data were processed

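Small RNA was sequenced from 24 single whole-body female terminal larvae of Camponotus floridanus. Per the labels' protocols, DNA and RNA including small RNA were extracted from each animal with an AllPrep kit, and libraries were built from 1000 ng of total RNA with the TruSeq small RNA kit. Size selection was on a Pippin Prep, and single-end reads were made on an Illumina HiSeq instrument. Per the submitters' processing notes, bcl2fastq 2.20 and Trim Galore 0.6.7 were used; the aligner, miRNA caller, genome build and counter are not given in the sources used here.

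Per the file headers, each library has a read count for every listed miRNA and the authors' value in RPM. The deposited count columns were identical whole numbers, and the deposited RPM equalled the count divided by the library's total, on a scale of reads per 1000000, to within 0.0050. The raw counts were used for every test. Each table had 924 entries for 459 hairpin names, and each name occurs in a first and in a second block of the table. The blocks were kept as the first-listed and second-listed mature form of the hairpin, since their counts differ; the headers do not say which is the 5p or 3p arm. A name repeated within a block, which happened for 3 names, was collapsed to its maximum per library. The rule set beforehand collapsed rows of a mature miRNA name to their maximum. Its use only within a block was decided once the tables had been seen, and the maximum over both blocks is given as an alternative. This left 918 forms, of which 101 had 0 reads in all libraries. The kit's protocol adds no molecular identifiers that the sources mention, so reads are not independent molecules, and floors of 3 reads cover counting error only.

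Forms with at least 10 reads in at least 12 of the 24 libraries were tested, which left 336 forms (233 first-listed and 103 second-listed) with 99.97% of the reads. Of these, 57 forms in 23 groups had identical counts in all 24 libraries, so reads of near-identical hairpins cannot be assigned to a single locus. Library sizes were scaled by TMM. The slope on length in units of 1000 µm, its squared term, and the largest against the smallest class were tested with edgeR 4.0.16 (quasi-likelihood F tests, robust, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. CPM is the count per 1000000 reads. It is given after TMM scaling for size classes, named forms and outlying larvae, and over the library total for floors, forms that separate libraries or larvae, and the hairpin pair. A percent is of all counted reads of a library. The ratio of the forms of a hairpin was tested with limma 3.58.1 on log2 of the counts plus 0.5, in place of a ratio of named arms. Correlations used two-sided permutation tests with 100000 resamples, and exact tests where fewer than 10 values were compared. The first principal component was taken from log2 CPM with a prior count of 2.

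The tests, the filter, the size classes and the rule for named miRNAs were chosen before the data were examined. That rule took up to 12 miRNAs per direction by smallest adjusted p, the 10 most abundant, a list of well-studied miRNAs and those passing the other tests. The names in the counts hold a scaffold and a running number with no position. None of the 459 matched the RefSeq table of Cflo_v7.5, which lists 14020 genes and 0 of the miRNA biotype, so the identifiers are not paired with miRNA names. For this reason 2 rising and 2 falling identifiers are printed, and the preset lists of miRNA families, clusters and tissue markers were not tested. Other identifiers in the closing section were chosen after their values were seen.

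No 2 libraries agreed within sampling noise: over 276 pairs the smallest chi-square per degree of freedom was 28.8. The sets of 9 and 15 libraries were found in the counts, as the widest gap in the log2 CPM of any tested form that left at least 5 libraries on each side. The labels give no library or sequencing batch.

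The tests were checked on simulated counts for the same libraries, with 1 run per setting. Simulated forms varied independently of each other and without a difference between library sets, so false calls from shared variation were not covered. With shuffled lengths, the real counts gave up to 14 slope calls. With no form changed, the slope test called 0 of 336 forms. With 60 changed forms it recovered 45% of slopes of 0.2, 70% of 0.4 and 100% of 0.8 log2 units per 1000 µm, with 1 false call among 44. The test of size classes recovered 40%, 70% and 100% for the same sizes, and the squared term 0%, 60% and 95%. For the ratio test 30 hairpins were changed before the count filter, which 98 hairpins passed. Of the changed hairpins that passed the filter, it recovered 10%, 75% and 90%. Slopes of 0.2 or less were thus often missed at this sample size.

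Alternatives covered other scaling factors, DESeq2 1.42.0, limma-voom, rank tests, count filters, ways of joining the forms of a hairpin, transformed lengths, covariates including a surrogate variable from sva 3.50.0, and leaving out each larva in turn. Alternatives that use the library sets, drop abundant forms or merge identical forms were added after the data had been seen.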

Results

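MicroRNAs were sequenced from the whole bodies of 24 female terminal larvae of the Florida carpenter ant (Camponotus floridanus), an ant whose workers differ widely in body size. The terminal larva is the last larval stage before pupation. The labels give each larva its own length, from 4648.07 to 7598.06 µm, and name neither a treatment nor a colony. The series belongs to a study of 48 larvae that examined DNA sequence, DNA methylation, gene expression and miRNAs as contributors to worker size, and 24 miRNA libraries were analysed here. Each library came from a different larva, so every larva was a biological replicate along a continuous axis of length. For a contrast of the ends, the larvae were also divided into 3 size classes of 8 by labelled length. The smallest class spanned 4648.07 to 5502.35 µm, the middle class 5690.32 to 6689.42 µm and the largest class 6797.79 to 7598.06 µm.

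The counts covered 459 hairpin names, each built from a scaffold and a running number, and each with a first-listed and a second-listed mature form. The first-listed forms held most of the reads, and the second-listed forms held 5.01% of them. Neither a miRNA family nor an arm was stated, and 0 of the 459 names matched the RefSeq gene table of the species, so forms are described by abundance, with 2 rising and 2 falling identifiers printed. Total counts per library ran from 881734 to 6128791, with a mean of 3186120 ± 1704977 reads (SD, n = 24). Between 488 and 656 forms had at least 1 read in a library. A count of 0 allowed a level of up to 0.489 CPM in the deepest library and 3.40 CPM in the shallowest, which covers counting error only.

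A small number of miRNAs made up most of each library. The most abundant form held 12.6% ± 2.16 of the reads (SD, n = 24), the 5 most abundant held 52.8% ± 2.84, and the 20 most abundant held 80.8% ± 2.33. The libraries fell into sets of 9 and 15 that were not given in the labels. The 9 libraries had a mean of 1338546 ± 455827 reads and the 15 libraries a mean of 4294665 ± 1070470 reads (two-sided exact permutation test, p = 2.29e-06). In 4 forms all 9 libraries lay above all 15, with median levels 14.3-fold to 71.5-fold higher. Mean larval length was 6059 ± 786 µm in the 9 and 6222 ± 1021 µm in the 15 (two-sided exact permutation test, p = 0.683). The set of 9 held 5 of the 8 middle-sized larvae and 2 of the 8 in each end class. Values within the sets, or with the set as a covariate, are therefore given beside the main results.

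**Figure D1:**
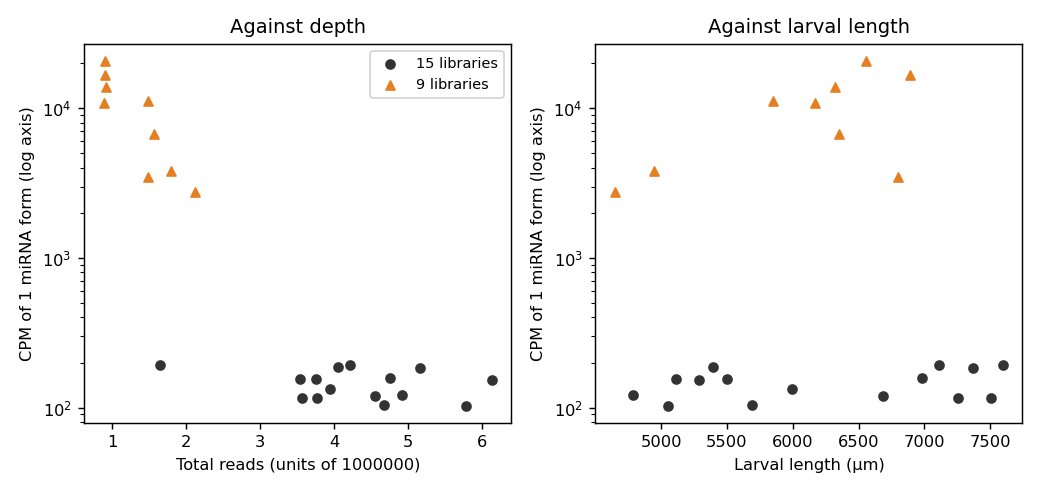
Level of the miRNA form that separated the library sets most widely, in CPM on a log axis, against total reads (left, axis in units of 1000000 reads) and larval length in µm (right), with 1 point per larva. The 9 libraries (triangles) lay at 2738 CPM or higher and the 15 libraries (circles) at 193 CPM or lower. The sets overlapped in length, but the 9 ran only from 4648 to 6893 µm, and all longer larvae were in the 15.

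The first comparison asked which miRNAs changed in abundance with larval length. Of 336 forms tested, 39 rose and 30 fell with length, together 20.5% of those tested. The second most abundant form in the larvae was among those that rose, from 8.92% ± 1.56 of all reads in the smallest class to 13.8% ± 2.23 in the largest (SD, n = 8 each). The rising forms together held 13.99% ± 1.89 of the reads in the smallest class, 17.9% ± 3.44 in the middle class and 20.4% ± 2.53 in the largest. The falling forms held 4.57% ± 0.201, 3.77% ± 0.561 and 3.08% ± 0.217 of the reads in the same order. These forms were selected on the same libraries, so their shares are not independent evidence of direction.

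The slope of each form was tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. At an unadjusted p under 0.05 there were 108 forms, against 16.8 expected by chance. The 39 rising forms came from 31 hairpins, with 35 distinct count profiles, since some hairpins had identical counts, and had a median slope of 0.35 log2 units per 1000 µm, with an interquartile range of 0.24 to 0.42. Over the observed span of 2950 µm the fitted line gives a median fold of 2.07, and 21 rising forms exceeded 2-fold on that line. The 30 falling forms came from 23 hairpins, with 28 distinct profiles, and had a median slope of -0.28, with a range of -0.52 to -0.16. Over the same span the fitted line gives them a median ratio of 0.565, and 8 fell by more than 2-fold on that line. These are fitted values, not ratios between individual larvae. Class means were in order in 26 of the 39 rising forms and in 28 of the 30 falling forms. Without the larva of replicate 7, the second shortest at 4783.45 µm, 20 forms rose and 32 fell, and without that of replicate 5, at 5850.88 µm, 24 rose and 39 fell. With no scaling factor beyond the library total, 24 forms rose and 41 fell.

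**Figure D2:**
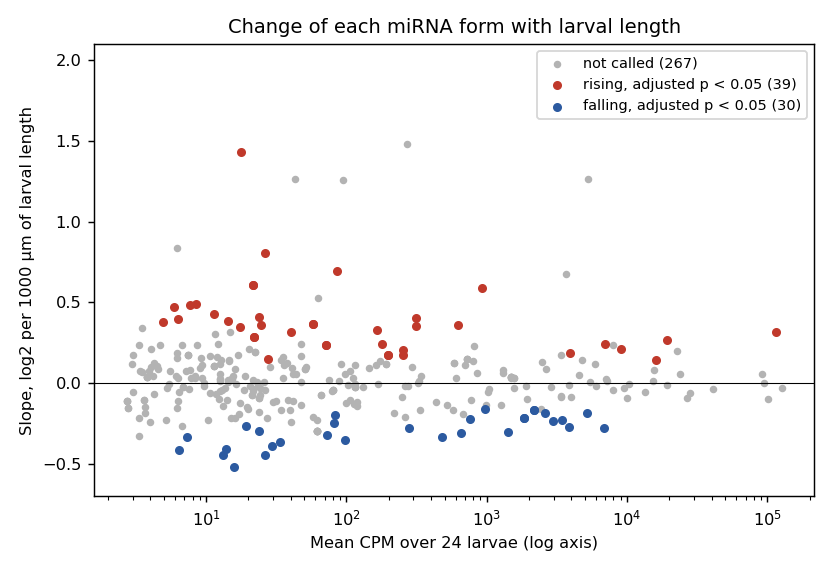
Slope on larval length, in log2 units per 1000 µm, against mean CPM over 24 larvae on a log axis, with 1 point per tested miRNA form. The 39 forms that rose are red, the 30 that fell are blue, and the 267 that did not pass an adjusted p of 0.05 are grey.

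Of the 20 most abundant forms, 4 passed by edgeR, and each of the 4 rose. The second most abundant form had a slope of 0.31 (SE 0.060, adjusted p = 0.000427), or 1.90-fold over the span of lengths, and its slope was 0.33 in the 9 libraries and 0.30 in the 15. The second-listed form of the same hairpin, ranked 20, rose with a slope of 0.21 (SE 0.069, adjusted p = 0.0367). The forms ranked 12 and 13, from a pair of hairpins on a single scaffold, rose with slopes of 0.27 (SE 0.043, adjusted p = 8.4e-05) and 0.14 (SE 0.052, adjusted p = 0.0487). In the 9 and the 15 libraries the slopes were 0.31 and 0.23 for rank 12, 0.14 and 0.11 for rank 13, and 0.23 and 0.21 for rank 20. The calls of ranks 2 and 12 held without any single larva. Those of ranks 13 and 20 were lost in 15 and 8 of the 24 fits that left out a larva, with adjusted p up to 0.145 and 0.163. The most abundant form had a slope of -0.03 (SE 0.066, adjusted p = 0.802).

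The rising form with the smallest adjusted p was the second-listed form of hairpin NW_020229414.1_22884, whose first-listed form ranked 13. Its level went from 462 ± 79.7 CPM in the smallest class to 631 ± 102 in the middle and 768 ± 68.2 in the largest (SD, n = 8 each), a slope of 0.36 (SE 0.049, adjusted p = 2.21e-05, edgeR). The first-listed form of NW_020229838.1_37076 went from 501 ± 103 to 1097 ± 322 and 1172 ± 136 CPM, a slope of 0.59 (SE 0.087, adjusted p = 3.18e-05, edgeR). Its straight line gives 3.31-fold over the span, but most of the rise lay between the smallest and the middle class. The squared term of this form was -0.26 (unadjusted p = 0.0114, adjusted p = 0.484, edgeR). Among falling forms, the first-listed form of NW_020229436.1_23921 went from 837 ± 115 to 621 ± 37.7 and 511 ± 46.0 CPM, a slope of -0.31 (SE 0.045, adjusted p = 2.77e-05, edgeR). The second-listed form of NW_020229841.1_37652, which ranked 36, went from 4678 ± 454 to 3840 ± 511 and 3106 ± 448 CPM, a slope of -0.27 (SE 0.045, adjusted p = 9.03e-05, edgeR). The lowest count behind any of these values in any library was 489 reads. Each kept its direction in both library sets. The slopes in the 9 and in the 15 were 0.52 and 0.29 for the first of the 4 forms, 0.64 and 0.57 for the second, -0.29 and -0.35 for the third, and -0.27 and -0.30 for the last.

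**Figure D3:**
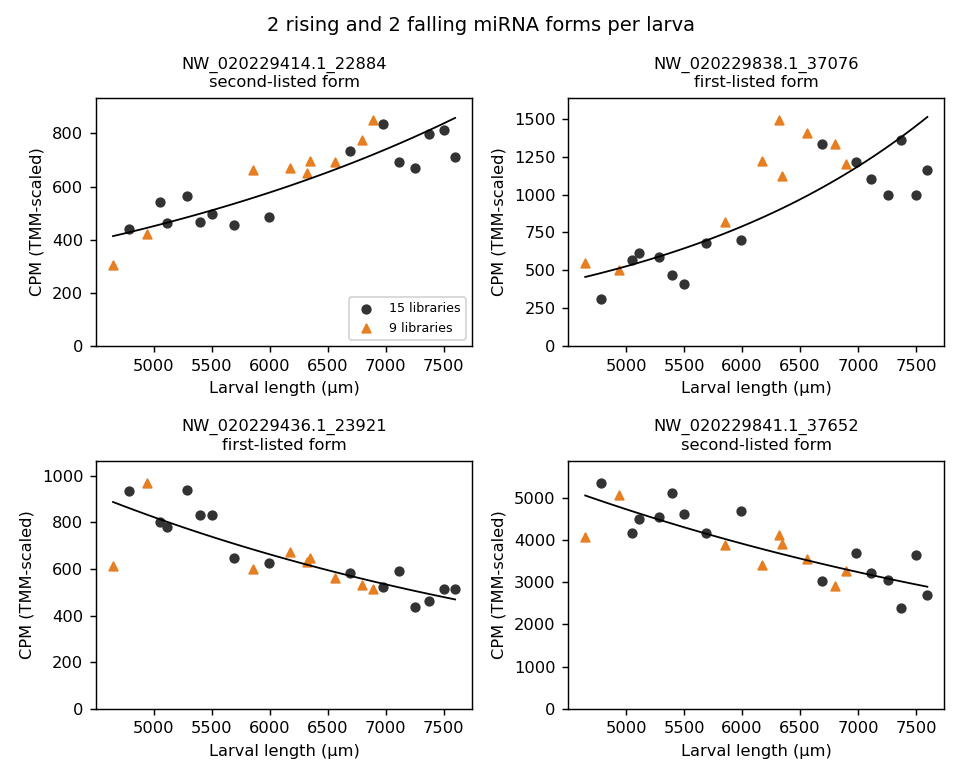
CPM after TMM scaling against larval length in µm for 2 rising (top) and 2 falling (bottom) miRNA forms, with 1 point per larva, triangles for the set of 9 libraries and circles for the set of 15. Each line has the fitted slope and passes through the mean log2 CPM at the mean length; the top pair rises and the bottom pair falls in both sets.

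Within the library sets, 68 of the 69 forms that changed with length had the pooled sign of slope in the 9 libraries and 69 had it in the 15. The 69, the named forms among them, were called on these same libraries, so this match was largely set by the selection. Fitted alone, the 15 libraries gave 22 rising and 26 falling forms by edgeR, and 44 of the 69 were among them. Each of these 48 forms had the same sign of slope in the 9. The 9 libraries alone gave 7 rising and 12 falling forms, with 16 of the 69 among them, and each of these 19 had the same sign in the 15. Over all 336 forms the signs matched between the sets in 241 (71.7%). With the library set as a covariate, 46 forms rose and 41 fell, and 68 of the 69 remained.

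The slopes of the mature forms of a hairpin were correlated. Among 103 hairpins with both forms tested, the slopes of the first-listed and second-listed forms had a Pearson r of 0.828 and a Spearman rho of 0.613 across hairpins, which are not independent replicates (permutation test, p = 1e-05 for r, the smallest possible). Both forms of a hairpin were counted in the same libraries, so this correlation is no separate support for a link with length. A pair of hairpins had slopes of 1.26 to 1.48 in both forms, which can weigh on r. The slopes had the same sign in 70 of the 103 hairpins (68.0%). The first-listed form changed with length in 30 of these hairpins and the second-listed form in 21. Both did in 15, each time with the same sign. The ratio of the first-listed to the second-listed form was then tested against length with limma, to ask whether larger larvae use a different arm. Of 103 hairpins, 0 passed, and 12 had an unadjusted p under 0.05 against 5.15 expected; no other tool was run. With the library set as a covariate 2 hairpins passed, and with a pseudocount of 5 in place of 0.5, 1 passed.

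The contrast of the largest with the smallest class gave a result of similar size that assumes no straight line. By edgeR, 33 forms were higher and 24 were lower in the 8 largest larvae than in the 8 smallest, and 56 of these 57 had also changed along length. The smallest adjusted p, 7.68e-06 by edgeR, was shared by the first-listed form of NW_020229436.1_23921, with a log2 difference of -0.71 (SE 0.091), and that of NW_020229838.1_37076, with a log2 difference of 1.23 (SE 0.16). In 8 forms every large larva lay above every small larva, and in 6 forms every large larva lay below. Chance gives such a separation in 0.0155% of forms, or 0.0522 of the 336. With the library set as a covariate, 65 forms differed.

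A squared term of length asked whether middle-sized larvae stood apart from both ends. By edgeR, 0 of 336 forms passed, 26 had an unadjusted p under 0.05 against 16.8 expected, and DESeq2 also gave 0. Since more of the middle-sized larvae were in the set of 9, the term was refitted with the library set as a covariate; edgeR again gave 0, with 10 forms at an unadjusted p under 0.05. Without a filter on low counts 7 forms passed, and without the larva of replicate 4, the shortest at 4648.07 µm, 1 passed.

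As computed by the planned tests, library-wide measures did not pass against length over the 24 larvae. In this family of 4 relations every Benjamini-Hochberg adjusted p was 0.411 for Pearson's r and 0.468 for Spearman's rho, by two-sided permutation tests. Total reads had r = -0.175 (p = 0.411) and rho = -0.161 (p = 0.450), and Shannon diversity, 4.87 ± 0.107 bits (SD, n = 24), had r = -0.193 (p = 0.367) and rho = -0.316 (p = 0.133). The share of the most abundant form had r = -0.278 (p = 0.185) and rho = -0.240 (p = 0.258), and the first principal component, with 31.4% of the variance, had r = 0.187 (p = 0.381) and rho = 0.155 (p = 0.468). With each form scaled to unit variance, the first principal component had r = 0.501 (permutation p = 0.0136, not adjusted). Without the 2 larvae farthest from the median length, r was -0.178, -0.185, -0.254 and 0.171 in the same order.

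Within the library sets these relations took other values. For all but diversity, both sets had the pooled sign and lay farther from 0 than the pooled r. No test with the set as a covariate was run on them. The first principal component separated the sets completely, with scores of 0.790 to 14.4 in the 9 and -9.25 to -0.397 in the 15, so its pooled r mixes the difference between sets with length. In the 9 libraries alone, total reads had r = -0.767 (two-sided exact permutation test, p = 0.0121) and the first principal component r = 0.705 (exact p = 0.0334), without adjustment for the number of relations. In the 15 libraries the same relations had r = -0.447 (permutation p = 0.0907) and r = 0.405 (permutation p = 0.133). The share of the most abundant form had r = -0.667 (exact p = 0.0511) in the 9 and r = -0.442 (permutation p = 0.0991) in the 15. Diversity had r = 0.295 (exact p = 0.458) in the 9 and r = -0.384 (permutation p = 0.156) in the 15.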

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

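The tests with the library set or between library sets were chosen after the data had been seen. Fits with no scaling factor, and fits without each larva in turn, were chosen before the data were examined. Their use below, on reads taken by abundant miRNAs and on the larva of replicate 14, was decided after the data had been seen. The search for outlying larvae covered 33 sets of 8 values, from 11 measures in 3 size classes, and picked out 4. Chance alone picks out about 1 in 20 sets when a measure is chosen without regard to its values. The most uneven forms were put among the measures for their unevenness, so that rate does not hold for them. The 4 are thus not evidence of an excess.

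Among the largest class, the larva of replicate 14 (7255.63 µm) stood far above the other 7 in a pair of forms on a single scaffold, which were among the measures because they were the most uneven across larvae. In the first, 75.9 CPM stood against 0.722 to 4.55 CPM, a gap of 0.949 of the whole range. In the second, 297 CPM stood against 11.1 to 19.4 CPM, a gap of 0.971 of the range. The second form was among the 39 that rose with length, with a slope of 0.81 (adjusted p = 0.0411, edgeR). Without that larva its slope was -0.03 (adjusted p = 0.915), so its call rested on a single animal.

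The larva of replicate 2 (6892.55 µm) had a diversity of 5.08 bits against 4.74 to 4.88 bits in the other 7 of the largest class, a gap of 0.592 of the range. The same larva scored 14.2 on the first principal component against -5.97 to 3.12, a gap of 0.549 of the range. Its library was among the shallowest, with 903494 reads, and belonged to the set of 9.

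The change of many miRNAs with larval length was set against 3 other explanations. Of 100 assignments of the lengths to the larvae, 1, the real assignment, gave 69 or more forms, and the highest of the others gave 14. This argues against a random ordering of the larvae as the source, though 1 of 100 is the smallest share that so few assignments can give. A difference between library sets would end the calls once it is in the model. With the library set as a covariate, 98.6% of the 69 forms still passed. All 48 forms that passed in the 15 libraries alone had the same sign in the 9. With log10 reads as a covariate, 61 of 69 passed. Total reads fell with length in both sets (r = -0.767 in the 9 and -0.447 in the 15), so a depth effect could give the same sign in both. No model held the set and log10 reads together, so depth within the sets was not separated from length. Abundant rising miRNAs taking the reads would push all other forms down by a like amount when no scaling factor is used. The median slope of all 336 forms was then -0.0235 (SD 0.261), against -0.317 for the falling forms, which argues against it for the falling forms. Of the 39 rising forms, 24 still passed then. A downward shift would cost rising calls without making any, so that count does not decide the question. A link between miRNA abundance and larval length therefore stays as a hypothesis, with depth within the library sets still open. Such a link may run through age within the stage or through tissue proportions, neither of which was tested.

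For the contrast of size classes, 1 of 100 splits, the real split, gave 57 or more forms, and the highest of the others gave 6, which argues against chance splits. The contrast used the same larvae, and 56 of its 57 forms had also changed along length, so it is not a separate line of evidence. The squared term and the ratio of forms gave 0 in the real assignment, a count that every assignment reaches, so 100 of 100 says nothing about chance there; the highest other counts were 2 and 8.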

How the results depend on the processing

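The settings that use the library sets, merge forms by their maximum, count identical forms once, or drop the 10 most abundant or the 4 set-separating forms were chosen after the data had been seen. Counts of rising and falling forms stayed within 1.5 times the reported 39 and 30 in 46 of 54 settings, leaving-out fits aside. DESeq2 gave 45 and 39, with 68 of the 69 forms shared, and limma-voom gave 37 and 24, with 58 shared. With identical forms counted once, 36 rose and 27 fell. Rising forms numbered 24 with no scaling factor, 19 with at least 100 reads in all libraries (falling 17), 21 with only the higher-mean form per hairpin, 21 with the maximum of the forms, 22 in the 15 libraries only and 7 in the 9 only (falling 12). The filter and the joining of forms leave fewer forms to test, and the library sets leave fewer larvae; for the scaling factor the cause was not tested. Leaving out each larva gave 20 to 43 rising and 21 to 39 falling forms, and 48 to 67 of the 69 were kept; the lowest rising counts were 20 without replicate 7 and 24 without replicate 5. The contrast of size classes ranged from 46 to 64. The squared term gave 7 without a filter and 0 to 1 when leaving out each larva, with 1 without replicate 4. The ratio of forms gave 1 with a pseudocount of 5 and 2 with the library set as a covariate; the cause was not tested. The correlation with length of total reads was -0.767, that of the first principal component 0.705 and that of diversity 0.295, with its sign reversed, in the 9 libraries only. In the 15 the values were -0.447, 0.405 and -0.384, so for total reads and the first principal component both sets lay farther from 0 than the pooled value. Both measures differed strongly between the sets while mean length did not detectably differ, so the pooled values mix the difference between sets with length. The first principal component scaled to unit variance had r = 0.501 (permutation p = 0.0136), so its relation to length depends on that scaling. Of 252 refits of 5 slopes, those of the 4 named forms and of the second most abundant form, 249 kept direction and threshold, 3 fell short of the threshold and 0 reversed. The 3 were the first-listed form of NW_020229436.1_23921 (adjusted p = 0.0826) and the second-listed form of NW_020229841.1_37652 (adjusted p = 0.0665) in the 9 libraries only, and that of NW_020229414.1_22884 (slope 0.13, adjusted p = 0.0774, edgeR) under the maximum of the forms. Under the sum of the forms the latter slope was 0.15 against 0.36; both settings follow its more abundant first-listed form. No scaling moved the median slope of all forms by over 0.1. No library was shallow enough for the planned setting that drops shallow libraries, so it was not run, nor were the list tests. Depth limits forms near the floor of 3 reads, up to 3.40 CPM in the shallowest library.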

Other observations

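All identifiers in this part, and the tests on library sets, on the hairpin pair and on the identical forms, were chosen after the values had been seen.

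A pair of hairpins with nearby running numbers on a single scaffold varied widely between larvae. The first-listed form of the more abundant hairpin, ranked 30, ran from 173 CPM in the larva of replicate 9 to 43387 CPM in that of replicate 11, a 251-fold range, with at least 621 reads in every library. The median range over the 336 tested forms was 3.20-fold, and the 4 forms that separate the library sets had ranges of 33.4-fold to 480-fold. The first-listed form of the other hairpin ran from 3.21 to 2074 CPM, with the same larvae at its ends. Across the 24 larvae the log2 CPM of these forms had a Pearson r of 0.958 and a Spearman rho of 0.917 (permutation p = 1e-05 for each, the smallest possible). Without the 2 larvae farthest from the median r was 0.931, and within the library sets it was 0.976 in the 9 (exact permutation p = 7.99e-05) and 0.936 in the 15 (permutation p = 1e-05). The 4 forms of the pair had slopes of 1.26 to 1.48 log2 units per 1000 µm with adjusted p between 0.0461 and 0.0640 (edgeR), so 1 of them passed. That form had the steepest slope of the 39 rising forms, 1.43 (SE 0.50), and its call was lost in 16 of the 24 fits that left out a larva, with adjusted p up to 0.116. It was thinly counted, with a median of 5.20 CPM and a lowest count of 2 reads, under the floor of 3 reads. Its slope was 2.76 (SE 0.87, unadjusted edgeR p = 0.0144) in the 9 libraries and 0.60 (SE 0.30, unadjusted edgeR p = 0.0678) in the 15, and 1.06 (SE 0.37, adjusted p = 0.0414) with the library set as a covariate.

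The forms that separated the sets of 9 and 15 libraries were the first-listed forms of NW_020229223.1_2442, NW_020229226.1_3055, NW_020229336.1_17160 and NW_020229669.1_32737, with medians 71.5-fold, 58.3-fold, 14.3-fold and 48.7-fold higher in the 9. Of the 15 larvae, all low in these forms, 9 had a length inside the range of the set of 9, which argues against larval length as what separates the sets. Within the 9, the log2 CPM of the widest-separating form had r = 0.618 with length (exact permutation p = 0.0789; rho = 0.50, exact p = 0.178) and r = -0.878 with log10 reads (exact p = 0.00472), and length and depth were themselves correlated there. A difference between library sets or in depth stays open: the 9 had fewer reads, and 73 of 332 other forms differed between the sets, against at most 8 in random splits of the same sizes. The sets were themselves chosen from the counts by their widest gap. Random splits were not chosen in that way, so forms that vary together could give such an excess. A library or sequencing batch may be a candidate source, but the labels name none, and no biological explanation other than larval length was tested.

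A group of 6 first-listed forms with identical counts, so that their reads cannot be told apart, had separate low and high larvae. In 10 larvae the level was 3.05 to 14.3 CPM, and in 14 larvae it was 32.0 to 150 CPM. Of the 10 low larvae, 8 had a length inside the range of the high larvae (mean length 6303 ± 968 µm in the low and 6059 ± 915 µm in the high, exact permutation p = 0.532), which argues against length as what separates them. Both levels occurred in both library sets, with 3 low larvae among the 9 and 7 among the 15, which argues against a difference between library sets. Family or colony of the larva could give such levels, for instance through a sequence variant, but it cannot be told apart here, since the labels give it for 0 larvae.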
